A study of Mus musculus with 64 samples.

How the data were processed

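Striatal tissue of 16 mice at about 50 days of age was profiled by RNA sequencing, 8 labelled Csnk1e knockout and 8 labelled wild type, all without treatment. Per the labels' protocols, punches of both hemispheres were pooled per mouse, poly(A) libraries were made with a stranded TruSeq kit, and single-end reads of 50 bases were sequenced on 4 lanes, 2 on each of 2 flow cells. The punch diameter is given as 3 mm in the design text and as 2.5 mm in the extraction protocol, and the 2 statements were left as they stand. The sex of the mice and the part of Csnk1e that was deleted are not given in the sources used here.

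The deposited files hold whole-number read counts per gene, 1 file per mouse and lane, 64 in all. The submitters' processing notes name FastQC 0.10.1, TopHat2 2.0.0, HTSeq 0.6.1p1, edgeR 2.14 and the build mm10, without stating the role of each. The gene annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping or antisense genes may not be told apart, and paralogs with near-identical sequence can share or lose reads. Each file lists 23420 genes and 5 summary rows, which were left out of library sizes and tests. Over the 16 mice, 18.0% to 19.8% of the reads fell in no gene, 0.77% to 0.83% were ambiguous and 21.1% to 22.9% had more than 1 alignment. Gene positions were taken from GENCODE M21 on GRCm38, the assembly that mm10 names, and 23234 genes were positioned by symbol, older symbol or RefSeq entry.

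The 4 lanes of a mouse are runs of 1 library. Their counts had a chi-square per degree of freedom of 1.01 to 1.03 within a mouse, against 6.20 to 37.2 for 56 pairs of mice of 1 labelled genotype, so lanes were summed and the mouse was the replicate. Gene reads per mouse ran from 22088005 to 30238947. Reads carry no molecular identifiers, so the counting error alone understates the error of a value, and the spread between mice was used throughout.

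Labelled genotypes were compared with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, with TMM scaling and no covariate, on 15446 genes kept by filterByExpr, which held 99.96% of gene reads. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Levels are CPM, read counts scaled to a common library total, on TMM-scaled library sizes, and log2 fold changes are labelled knockout minus labelled wild type with 95% confidence intervals. Gene lists were fixed before the data were examined. They covered the casein kinase family, the circadian clock, direct and indirect pathway neurons, striatal interneurons, dopamine and DARPP-32 signalling, the opioid system, canonical Wnt signalling, activity-regulated genes, glutamate receptors, GABA synthesis and receptors, interferon-stimulated genes and MHC class I. Lists for other cell types covered oligodendrocytes and their precursors, astrocytes, microglia, endothelial and mural cells, choroid plexus, ependymal cells, cortical, septal and thalamic neurons and blood. Lists for RNA quality covered heat shock, cytosolic ribosomal proteins, nuclear oxidative phosphorylation and mitochondrially encoded genes. Of the 28 lists, 26 had at least 3 tested members and were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. A list score is the mean over members of log2 CPM with a prior count of 2, centred per gene. Scores of 13 cell type lists were compared by an exact permutation test over all 12870 assignments, two-sided.

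Genes named in the text followed a rule fixed with the design. It took Csnk1e, the 10 genes with the smallest p because fewer than 5 genes were called, the 2 members of each list with the smallest p, and Csnk1d, Csnk1a1, Per1, Per2, Ppp1r1b, Oprm1, Drd1a and Drd2. It gave 69 genes. Called genes within 5 Mb of Csnk1e were compared with the rest by Fisher's exact test. Alternatives were RLE and upper quartile scaling, DESeq2 1.42.0, limma-voom with quality weights, the edgeR exact test, 2 other low count filters, the mouse number as a replicate block, covariates, single flow cells, lanes kept apart, leaving out each mouse and leaving out the genes near Csnk1e. A surrogate variable came from sva 3.50.0. The sex of a library, used as a covariate, was read from Xist and 4 Y-linked genes.

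The test was tried on simulated counts for 15446 genes in 8 against 8 libraries, with 200 genes changed. It recovered 37 of 50 genes at 1.25-fold, 42 of 50 at 1.5-fold, 48 of 50 at 2-fold and 49 of 50 at 4-fold, and 6 of its 182 calls were unchanged genes. The simulated counts were drawn for each gene on its own from its fitted mean and spread, with every library labelled correctly. Variation shared between genes and a conflict of labels with Csnk1e were left out. These rates therefore cannot say which changes the real comparison would miss. Permutation tests of single patterns were run with numpy 2.4.6 in Python 3.11.15, with ranks and adjusted p-values from scipy 1.17.1.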

Results

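The series asked how loss of Csnk1e, which encodes casein kinase 1 epsilon, a kinase that acts on the PERIOD clock proteins, alters gene expression in the striatum of untreated mice. Poly(A) RNA of 16 mice was sequenced, 8 labelled knockout and 8 labelled wild type. The labels name 16 separate mice. Libraries held 22088005 to 30238947 gene reads, and 17953 to 18339 genes had at least 1 read.

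Csnk1e, on chromosome 15 from 79417856 to 79455566 in GRCm38, did not follow the genotype labels. In the libraries labelled knockout 1 to 8 it stood at 72.2, 75.4, 77.2, 76.8, 79.5, 38.0, 44.6 and 39.2 CPM. In the libraries labelled wild type 1 to 8 it stood at 42.8, 44.9, 42.1, 83.9, 77.9, 86.2, 72.2 and 42.8 CPM. Raw counts ran from 923 to 2315 reads per library, so counting error is small beside these differences. The means were 62.9 ± 18.6 CPM (SD, n = 8) for the labelled knockouts and 61.6 ± 20.2 CPM (SD, n = 8) for the labelled wild types, a log2 fold change of 0.03 with a 95% interval from -0.40 to 0.45 and adjusted p = 0.997 by edgeR. The 16 values left a gap between 44.9 and 72.2 CPM, with libraries of both labels on both sides. At the level that sorted them best, in either direction, 6 of 16 libraries still lay on the side of the other label, and 98.0% of all 12870 ways to label 8 of the 16 libraries did as well or better. By the library number in the labels, labelled knockouts were above the gap up to number 7 and below it from number 9. Labelled wild types were below it up to number 8, above it from 10 to 16 and below it at 17. The labels were kept as given. Since the deleted part of the gene is not given in the sources used here, the gene-level count may include reads that a deletion leaves in place. Every direction below is between libraries labelled knockout and labelled wild type, and the targeted gene goes against these labels.

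**Figure D1:**
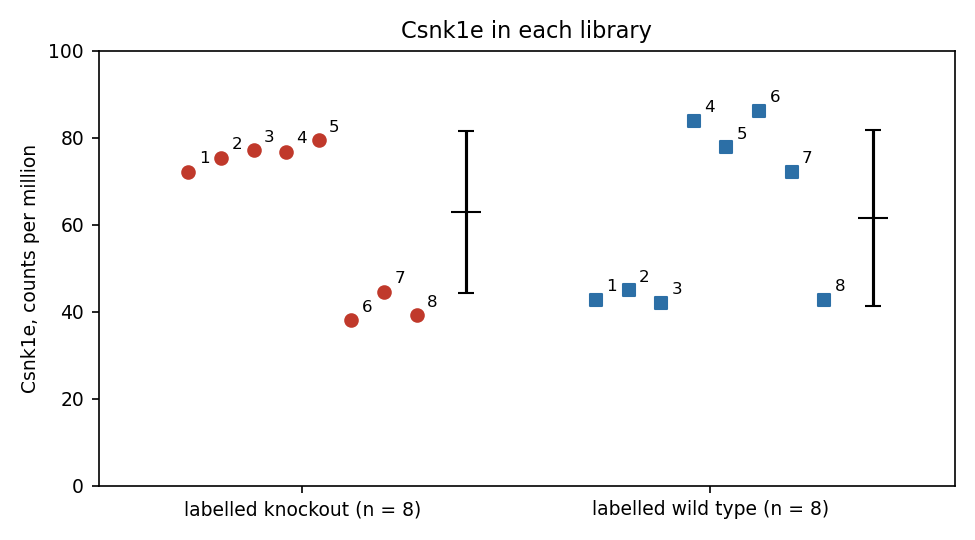
Csnk1e in CPM on the vertical axis for the 8 libraries labelled knockout (circles) and the 8 labelled wild type (squares), each point with its mouse number, and bars for the mean and SD of each labelled group. Both labelled groups have libraries at or below 44.9 CPM and at or above 72.2 CPM.

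Among single genes, none passed the test between the labelled genotypes. Of 15446 genes, edgeR called 0 higher and 0 lower in the labelled knockouts, with 526 genes (3.41%) at an unadjusted p under 0.05, 295 higher and 231 lower. DESeq2 called 0 with 566 at that unadjusted level, limma-voom called 0 with 683, and the edgeR exact test called 0 with 449. The smallest adjusted p by edgeR was 0.997. The count of 526 rose to 909 without the library labelled knockout 7 and fell to 323 with the library number as a covariate. Smyd3, a lysine methyltransferase, had the smallest unadjusted p and stood at 27.7 ± 1.59 CPM (SD, n = 8) in the labelled knockouts against 24.8 ± 0.75 CPM (SD, n = 8). Gemin4, a component of the SMN complex, had a log2 fold change of 0.18 (SE 0.04), and Crebzf, a leucine zipper protein, had -0.16 (SE 0.04). The next by p were Nrg4 at 0.36, Plcb2 at 0.26, Pura at -0.26, Kif26b at 0.33, Igsf10 at 0.38, Maf at -0.20 and Zfp804b at 0.87 log2, the last at 0.79 CPM in the labelled knockouts. All 10 had adjusted p = 0.997 by edgeR. With lanes kept apart and the mouse as a random block, 8 genes were called higher and 16 lower, but that model counts the 4 lanes of a mouse partly as replicates.

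Casein kinase and clock transcripts did not pass the test. Of 14 tested casein kinase family members 0 were called, also 0 adjusted over the list alone. Csnk1d, the closest relative of Csnk1e, stood at 138 ± 5.94 CPM (SD, n = 8) against 141 ± 6.36 CPM (SD, n = 8), with a log2 interval from -0.10 to 0.05. Csnk1a1 had a log2 fold change of -0.04 with an interval from -0.13 to 0.05, Csnk1g1 had 0.08 and Vrk1 had 0.14. The median of this list was below 0 and its mean above 0, and camera put it lower with adjusted p = 0.928. Of 25 clock genes 0 were called, also 0 adjusted over the list alone. Per1 had 0.10 log2 with an interval from -0.18 to 0.39 and Per2 had -0.01 with an interval from -0.29 to 0.28, a sign that turned under several settings, among them limma-voom at 0.04. Nfil3 had -0.19 and Dbp had -0.12. The clock list had a median above 0 and a mean below 0, and camera put it higher with adjusted p = 0.928.

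No gene of dopamine and DARPP-32 signalling passed the test, and the list was called only with the preset correlation. Of 29 genes of dopamine and DARPP-32 signalling 0 were called, also 0 adjusted over the list alone, and 21 had a fold change above 0. Camera called the list higher with adjusted p = 0.0376, and the call was lost at adjusted p = 0.878 with an estimated correlation. At the preset correlation, the replicate block lost the call too, at camera adjusted p = 0.0725. The call also ended without any 1 of the libraries labelled knockout 2 and 8 and wild type 1, 2, 4, 6 and 8, at adjusted p = 0.0552 to 0.344. Its examples were Pde1b, a phosphodiesterase, at 0.14 log2 and Gng7, a G protein subunit, at 0.13. Ppp1r1b, which encodes DARPP-32, stood at 1120 ± 133 CPM (SD, n = 8) against 1080 ± 207 CPM (SD, n = 8). Drd1a had 0.09 log2 with an interval from -0.15 to 0.33 and Drd2 had 0.09 with an interval from -0.13 to 0.32. With 1 surrogate variable as a covariate, Ppp1r1b and Drd1a turned to -0.03 and -0.01.

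Of 12 opioid system genes 0 were called, also 0 adjusted over the list alone, and 10 had a fold change above 0. Camera called the list higher with adjusted p = 0.0399, lost at adjusted p = 0.535 with an estimated correlation. With the replicate block at the preset correlation it was lost too, at camera adjusted p = 0.0576. The call also ended without any 1 of the libraries labelled knockout 2, 4 and 8 and wild type 1, 3, 6, 7 and 8, at adjusted p = 0.0589 to 0.193. Penk, the proenkephalin gene, stood at 1060 ± 162 CPM (SD, n = 8) against 942 ± 111 CPM (SD, n = 8), and Oprm1, the mu opioid receptor gene, had 0.34 log2 with an interval from -0.04 to 0.73. Direct pathway markers had 0 of 9 called with Chrm4 at 0.11 and Sfxn1 at 0.05 log2, and camera gave adjusted p = 0.0905. That list was called higher without any 1 of the libraries labelled knockout 3, 5 and 7 and wild type 5 and 7, at adjusted p from 0.00176 to just under 0.05, the last without knockout 3. Indirect pathway markers had 0 of 9 called with Penk at 0.17 and Sp9 at -0.13, and camera gave adjusted p = 0.268, and 0.0233 without wild type 5. Striatal interneuron markers had 0 of 12 called with Slc5a7, the choline transporter, at 0.26 and Nos1 at 0.21, and camera gave adjusted p = 0.28. None of these 3 lists had a call adjusted over the list alone.

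**Figure D2:**
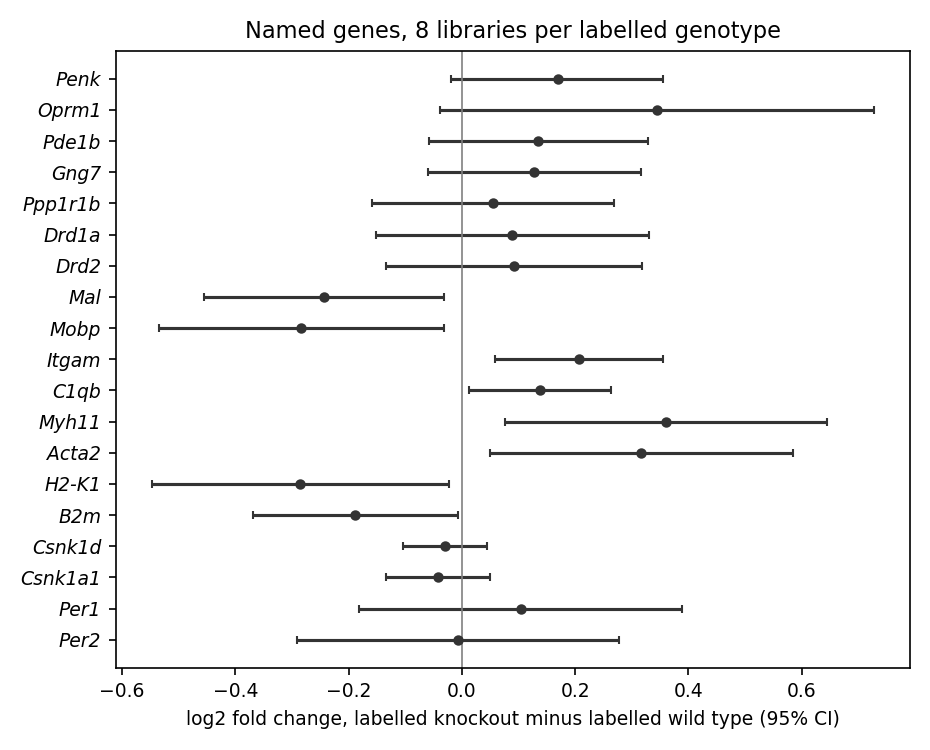
Log2 fold change of 19 named genes, labelled knockout minus labelled wild type, on the horizontal axis, with 95% confidence intervals from edgeR over 8 libraries per label. All 19 had an adjusted p above 0.99. The intervals of Penk, Oprm1, Pde1b, Gng7, Ppp1r1b, Drd1a, Drd2, Csnk1d, Csnk1a1, Per1 and Per2 include 0. Those of Mal, Mobp, Itgam, C1qb, Myh11, Acta2, H2-K1 and B2m exclude 0, but the intervals are not adjusted for the number of genes. These genes were also picked for the smallest p of their lists in these same libraries, which favours intervals that exclude 0.

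Among other cell types, the oligodendrocyte, mural and microglial lists were called by camera with the preset correlation and not with an estimated one. All 18 oligodendrocyte genes had a fold change below 0, with 0 called and 0 adjusted over the list alone. Camera called the list lower with adjusted p = 2.7e-06, lost at adjusted p = 0.878 with an estimated correlation. The myelin genes Mal and Mobp had -0.24 (SE 0.10) and -0.28 (SE 0.12) log2. All 10 mural cell genes had a fold change above 0, among them the smooth muscle genes Myh11 at 0.36 (SE 0.14) and Acta2 at 0.32 (SE 0.13), with 0 called and 0 adjusted over the list alone. Camera called the list higher with adjusted p = 4.71e-06, lost at adjusted p = 0.535 with an estimated correlation. Of 12 microglial genes 10 had a fold change above 0, with 0 called and 0 adjusted over the list alone, and camera called the list higher with adjusted p = 0.00203, lost at adjusted p = 0.878 with an estimated correlation. Itgam had 0.21 and C1qb 0.14 log2. The calls of these 3 lists held in each of the 16 fits that left out 1 library, but single libraries moved them by far. The microglial list came to adjusted p = 0.0499 without the library labelled knockout 1, whose score was 0.26, and to 0.0351 without wild type 5, whose score was -0.21. The oligodendrocyte list came to adjusted p = 0.00273 without wild type 7, at a score of 0.39, to 0.00182 without knockout 4, at -0.52, and to 0.000757 without knockout 8, at -0.37. The mural list came to adjusted p = 0.000171 without wild type 5 and to 0.000131 without wild type 8. By the exact permutation test of scores, 0 of 13 cell type lists differed, and the smallest p was that of the mural score at 0.023, adjusted p = 0.299. The libraries labelled knockout 1 and wild type 7 stood apart in choroid plexus transcripts, with scores of 3.84 and 4.40 against -1.25 to 0.70 in the other 14. Without these libraries, an alternative chosen after the data were seen, edgeR called 0 genes with 410 at an unadjusted p under 0.05.

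The remaining cell type lists had 0 called members and 0 adjusted over the list alone. Camera gave adjusted p = 0.37 for oligodendrocyte precursors, with Cspg4 at 0.19 and Matn4 at -0.19 log2, and adjusted p = 0.386 for astrocytes, with Ntsr2 at -0.13 and Gjb6 at -0.17. It gave adjusted p = 0.791 for endothelial cells, with Cldn5 at -0.13 and Flt1 at 0.11, and adjusted p = 0.268 for ependymal cells, with Mia at -0.62 and Foxj1 at -0.16. Cortical excitatory neurons had adjusted p = 0.124, with Neurod2 at -0.27 and Emx1 at -0.37. That list was called lower without any 1 of the libraries labelled knockout 3, 4, 5 and 7 and wild type 5 and 7, at adjusted p from 0.00726 to just under 0.05, the last without knockout 3. Septal and thalamic neurons had adjusted p = 0.791, with Tcf7l2 at -0.16 and Prkcd at 0.17. Choroid plexus genes had adjusted p = 0.928, with Prlr at -0.75 and Aqp1 at -0.45. These values rest on 2 libraries: they were 1.24 and 2.20 without wild type 7, where camera called the list higher at adjusted p = 0.03, and -2.13 and -2.24 without knockout 1, by label. Of the blood list only Alas2, at -0.05, was tested.

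**Figure D3:**
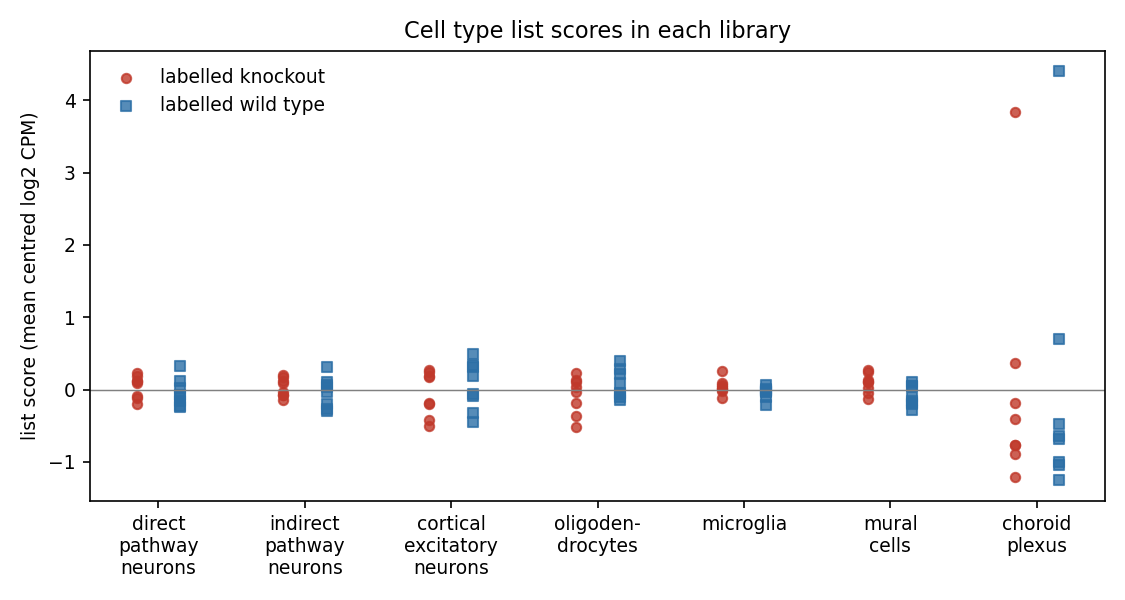
Score of 7 cell type lists, the mean over members of centred log2 CPM, on the vertical axis for the 8 libraries labelled knockout (circles) and the 8 labelled wild type (squares). For the choroid plexus, 1 library of each label stands apart at 3.84 and 4.40.

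Immune, synaptic and stress lists had no called member, also adjusted over the list alone. Of 11 MHC class I genes 10 had a fold change at or below 0, with H2-K1 at -0.29 (SE 0.13) and B2m, the class I light chain, at -0.19 (SE 0.09) log2. Camera called that list lower with adjusted p = 0.00873, lost at adjusted p = 0.878 with an estimated correlation, and it also ended without the library labelled wild type 1, whose score stood apart at 0.54, at adjusted p = 0.284 and without knockout 8 at adjusted p = 0.124. Interferon-stimulated genes had adjusted p = 0.238, with Ifih1 at -0.13 and Oasl2 at -0.17, and were called lower without the library labelled knockout 3 at adjusted p = 0.00364. Activity-regulated genes had adjusted p = 0.764, with Jun at -0.24 and Btg2 at 0.34, and were called higher without knockout 3, whose score stood apart at -0.48, at an adjusted p just under 0.05. Glutamate receptor genes had adjusted p = 0.584, with Grin3a at 0.24 and Gria1 at 0.10, and GABA genes had 0.355, with Gabra2 at 0.16 and Gabbr1 at 0.06. Canonical Wnt genes had adjusted p = 0.791, with Fzd8 at -0.25 and Tcf7l2 at -0.16, and their median was above 0 while their mean was below it.

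Of the RNA quality lists, 91 nuclear oxidative phosphorylation genes had a median of -0.02 log2, with Cox8a at -0.22 and Cox4i2 at 0.23. Camera called them lower with adjusted p = 0.0262, lost at adjusted p = 0.878 with an estimated correlation. The call also ended without any 1 of the libraries labelled knockout 1, 2, 4 and 6 and wild type 4, 6 and 8, at adjusted p = 0.0815 to 0.677. Heat shock genes had adjusted p = 0.46, with Hspa1a at -0.27 and its near-identical copy Hspa1b at -0.42. Since reads with more than 1 alignment were left out, reads of these copies may be missing from both counts. Others may be placed on the wrong copy. The 75 cytosolic ribosomal protein genes had adjusted p = 0.238, with Rps19 at 0.09 and Rps27l at -0.11, but were called higher without any 1 of the libraries labelled knockout 1, 2 and 4 and wild type 4, 6 and 8, at adjusted p = 0.000469 to 0.0499. These 3 lists had 0 called members and 0 adjusted over the list alone, and the files list 0 mitochondrially encoded genes.

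Genes around the targeted locus did not stand out between the labelled groups. Csnk1e itself did not follow these labels, so the test cannot decide whether genes near the locus differ with the targeted allele. Of 201 tested genes within 5 Mb of Csnk1e edgeR called 0, and 7 (3.48%) had an unadjusted p under 0.05, against 515 (3.40%) of the 15158 elsewhere. Fisher's exact test, two-sided, gave p = 0.845 for that difference.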

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

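The splits of the samples, the covariates for sex and for other cell types and the position test were planned, and the other tests in this part were chosen only after the values were seen. Outliers were sought in 202 groups of 8 values and 17 were found, where chance gives about 1 in 20.

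Csnk1e parts into separate levels inside both labelled groups. Ordinary spread between mice is argued against, since the separation of Csnk1e within both labelled groups ranked 1 of 15446 genes. Sex of the mice is argued against as well, since the 11 libraries with male-like transcripts alone hold a log2 gap of 0.68. Mislabelled libraries remain a possible explanation: at the best of all levels 6 of 16 libraries lie on the side of the other label. At the gap itself 9 do if low is read as knockout and 7 if high is. The side of each label changed along the library numbers. Up to number 8, labelled knockouts stood at 72.2 to 79.5 CPM and labelled wild types at 42.1 to 44.9 CPM. From number 9 to 16, labelled knockouts stood at 38.0 to 44.6 CPM and labelled wild types at 72.2 to 86.2 CPM. Number 17, labelled wild type, stood at 42.8 CPM. A deletion that leaves reads in place is argued against as the only cause if the labels are right. The labelled wild types, which would carry no deletion, stood at 42.1 to 44.9 CPM and at 72.2 to 86.2 CPM. Such a deletion together with mislabelled libraries was not tested. The labelled genotype and the library number interacted in Csnk1e by -0.14 log2 per number (exact permutation p = 0.00155, 12870 labellings). That test was prompted by these same values.

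The library labelled knockout 3 holds transcripts of both sexes. Its Xist stood at 1150 CPM, against 1180 to 1480 CPM in the other 4 female-like libraries, while Ddx3y, Kdm5d, Uty and Eif2s3y stood at 6.96, 2.91, 2.35 and 3.56 CPM. Reads from the X-linked copies of the Y-linked genes are argued against, since each gene was at least 7.22-fold above the highest other female-like library. Male RNA or reads mixed into a female library may account for it, as the 4 genes stood at a median of 8.74% of the male-like mean, between 6.64% and 11%. No biological explanation was tested.

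Choroid plexus transcripts stood apart in the libraries labelled knockout 1 and wild type 7, with scores of 3.84 and 4.40. Prlr stood at 23.7 and 45.5 CPM and Aqp1 at 12.6 and 19.0 CPM in these libraries. Choroid plexus tissue in the punch is a candidate explanation. In both libraries, 6 of 7 tested markers were at least 4-fold above the median of the other 14 libraries. These markers make up the score that set the libraries apart, so their count is no separate support. Ttr, the most abundant, stood at 1480 and 2150 CPM. In the other 14 its median was 6.28 CPM, with a range from 1.14 to 122 CPM. No biological explanation was tested.

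The remaining outliers are values far from the other 7 of their labelled group. In the library labelled wild type 5, Nrg4 stood at 3.09, Maf at 13.3, Grin3a at 22 and Itgam at 27.4 CPM, and the heat shock score at 0.30. Ifih1 stood at 8.21 CPM in wild type 4, C1qb at 74.0 CPM in knockout 1 and Cox8a at 337 CPM in wild type 8, by label. The activity-regulated score stood at -0.48 in the library labelled knockout 3, the MHC class I score at 0.54 in wild type 1 and the ependymal score at -1.16 in knockout 2.

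The labels gave 0 called genes, a count that all 100 splits drawn of the 6435 possible had to reach, so the splits decide nothing about it. The highest other split gave 46 genes, 0 of them sex-linked, and 3 of the 99 others gave any call. The 46 genes may point to a structure of the samples that the labels do not name, or to chance among many splits, and this was not tested. At an unadjusted p under 0.05 the labels gave 526 genes, and 58 of the 100 splits, the real one included, gave at least as many, with a median of 595 in the others and a range from 200 to 2234, so chance cannot be excluded for that number. With a covariate for unequal sex of the mice in the 2 genotypes 0 genes were called. By transcripts, 3 libraries labelled knockout and 2 labelled wild type were female-like. With a covariate for neighbouring tissue in the punches 0 were called too. That covariate was the first principal component of the other cell type scores, with 89.3% of their variance. It mainly set knockout 1 and wild type 7 apart, by label, at -3.87 and -4.48 against -0.67 to 1.30 in the others. It therefore followed choroid plexus transcripts and cannot stand for all neighbouring tissue. Neither sex nor tissue can be told apart from no effect, there being no call to lose. The position of called genes near Csnk1e has no call to test either (Fisher's exact p = 1.0).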

How the results depend on the processing

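The alternative without 2 libraries was chosen after the data were seen, and the others before. Over 75 results and 2397 comparisons, 2348 kept their direction and side of the threshold or, for a count, stayed within 1.5 times. Of 69 named genes, 62 never changed sign. Since 0 genes were called and most named genes were picked by p in these same libraries, such agreement was likely from the start. It is no evidence for a difference in any of them. Lanes apart gave 8 genes higher and 16 lower, and of the named genes Mal, Mobp and Cox8a were called there. The consensus correlation of 0.5 in that setting counts lanes partly as replicates, so its p-values can come out too small. How far this made the calls was not tested. All other settings called 0 genes in each direction, leaving out each mouse included (0 to 0). The mouse numbers name different animals and do not pair them. With each gene centred on its labelled group mean, same-numbered libraries correlated from -0.338 to 0.095. Of the 8 labelled knockouts, 0 correlated best with the labelled wild type of their own number. The replicate block gave 0 higher and 0 lower genes and 2 lists higher, in place of 4, and changed no other call of a count. The lists that lost their call were those of dopamine and DARPP-32 signalling and of the opioid system. With an estimated correlation 0 lists were higher and 0 lower, and with fry 0 and 0. Leaving out each mouse gave 2 to 6 lists higher (2 without wild type 1 and 2 without knockout 8) and 2 to 5 lower (5 without knockout 3), by label. A count that stayed close can hide other lists: 11 of 26 lists changed their call when some mouse was left out, 4 by losing it and 7 by gaining it, and each of the 16 fits changed at least 1 list. The Csnk1e log2 fold change turned sign with the library number (-0.018) and its value ranged from -0.04 to 0.11 when each mouse was left out. Its largest move was to 0.19 with limma-voom, at adjusted p = 0.935. Prlr turned to 1.24 without wild type 7, in a range from -2.13 when each mouse was left out. Aqp1 turned with DESeq2 (0.33), limma-voom (0.28), the replicate block (0.11), the sex covariate (0.28), the other cell type score (0.22), without wild type 7 (2.20, from -2.24 when each mouse was left out) and without the 2 choroid plexus libraries (0.41). Per2 turned with limma-voom (0.041), the replicate block (0.014), library number (0.074), flow cell 1 (0.028), lanes apart (0.008), without the 2 libraries (0.020) and ranged from -0.09 to 0.10 with a mouse left out. Alas2 turned with flow cell 2 (0.026) and ranged from -0.108 to 0.024 with a mouse left out. With 1 surrogate variable Ppp1r1b turned to -0.028 and Drd1a to -0.007. The cause of these turns was not tested. Zfp804b and Mia, at 0.79 and 0.69 CPM in the labelled knockouts, rest on few reads.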

Other observations

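The relations in this part were chosen after the data were seen, so p-values were adjusted over all 78 pairs of the 13 cell type scores. Of these, 7 had an adjusted p under 0.05 by Pearson's r and 6 by Spearman's rho. The direct and indirect pathway scores varied together across the 16 libraries, with r = 0.91 and rho = 0.91 (permutation p = 2e-05 and adjusted p = 0.00156 for each). Both varied against the cortical excitatory score. The direct pathway score had r = -0.80 (permutation p = 0.0003, adjusted p = 0.00624) and rho = -0.79 (permutation p = 0.0004, adjusted p = 0.00877). The indirect pathway score had r = -0.82 (permutation p = 0.0001, adjusted p = 0.00442) and rho = -0.83 (permutation p = 0.0002, adjusted p = 0.0078). Without the 2 libraries farthest from the median the 3 values of r were 0.86, -0.81 and -0.78. Within the labelled knockouts they were 0.87, -0.68 and -0.80, and within the labelled wild types 0.93, -0.88 and -0.85.

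Oligodendrocyte precursor and astrocyte scores had r = 0.80 (permutation p = 0.0002, adjusted p = 0.00442) and rho = 0.74 (permutation p = 0.00136, adjusted p = 0.0212), with r = 0.72 without the 2 farthest libraries, 0.74 within the labelled knockouts and 0.91 within the labelled wild types. Astrocyte and choroid plexus scores had r = 0.69 and rho = 0.72 (permutation adjusted p = 0.0139 and 0.0296). Without the 2 libraries farthest in the astrocyte score, that r was 0.40. Precursor and choroid plexus scores passed by rho alone, at 0.79 (permutation adjusted p = 0.00877). Microglial scores passed by r alone, at 0.69 with precursors and 0.65 with astrocytes (permutation adjusted p = 0.0468 each, and 0.23 by rho). Oligodendrocyte and astrocyte scores had r = 0.62 and rho = 0.63, which did not pass the adjustment (permutation adjusted p = 0.0894 and 0.114).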
